A study of Homo sapiens with 12 samples.

How the data were processed

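Messenger RNA of PMA-differentiated THP-1 cells was sequenced in 12 libraries, made from 1 µg of total RNA each with a stranded poly(A) kit, per the labels. The deposited values were read counts per gene for 58051 Ensembl genes on hg38, in 1 table for all libraries. Per the file headers, the authors counted exon reads per gene with featureCounts 2.0.3, for paired reads, with chimeric pairs left out and primary alignments only. No strand option was given in the file headers, so reads of antisense or overlapping genes cannot be told apart. Mates were counted separately by the option given, per the file headers, and 70.4% to 73.3% of the deposited counts from 1 to 19 were even. Of a read with several alignments 1 was counted, so values of near-identical copies (ORM1 and ORM2, PCDHB5 and its family, HLA and ribosomal protein genes) are uncertain. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.10b, BWA, Picard 2.27.5, FastQC, MultiQC 1.13 and Subread were also used. Which aligner made the counted alignments and which annotation release was used are not given in the sources used here. Of the 57447 genes also found in GENCODE 29, 96.2% had the same bounds there. A separate reference table of gene names held 56948 of the genes. No count in any library was found for 26598 genes, and mitochondrial genes had 0 counts in all 12 libraries.

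Counts-per-million values (CPM) and log2 fold changes were computed here from the deposited counts. Genes were filtered with edgeR's filterByExpr at its defaults, which left 17119 genes, and libraries were scaled by TMM. The groups were compared with edgeR 4.0.16 by its quasi-likelihood test in 1 fit of all 12 libraries with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method. Genes were called at an adjusted p under 0.05, two-sided. The comparisons were knockout against wild type with IFN-γ (the one the design text names) and without it, the IFN-γ response in each genotype, and the difference of the 2 responses. Depth set the precision: a floor of 3 counts was 0.102 to 0.127 CPM in a library. Folds against a group at 0 were taken against 3 counts over the group, and groups with 1 to 3 counts have a ratio with an exact 95% counting interval. Chi-square values per degree of freedom between replicate pairs of a group were 2.9 to 7.6, above counting noise for independent reads. Counting mates separately raises the value that counting noise alone gives, so how far the replicates exceed it is not known.

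Before the data were examined, 31 gene lists were fixed, and 30 could be tested, since the mitochondrial list had no counts. They were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over lists within a comparison. Blocks of 50 consecutive tested genes were tested by camera in both genotype comparisons and called where the direction was the same in both. The rule for named genes was also fixed then. In each comparison it named SDC3, the 8 largest rises and 8 largest falls among genes with an official symbol, an adjusted p under 0.05, at least 5 CPM in the higher group and no overlap of replicates (for the difference of responses, 5 CPM in 1 of the 4 groups and no overlap rule). It also named up to 4 members of every called list and of 7 lists chosen in advance (2 that rose and 2 that fell), and a panel of 16 genes whatever their result. For length, some of the largest changes and list members are left out, and a few genes that the rule named are not reported here; CLDN7 and the other members named beside a list follow the same rule.

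The fits were tested on simulated data. Counts were drawn independently for each gene around the wild-type means with IFN-γ in all libraries, with the spread that edgeR fitted by expression level. Only 50 genes at each fold, a list and a block of 50 genes were changed. In the real comparison with IFN-γ 47.2% of genes were called, so the rates found here may not hold for it. For knockout against wild type with IFN-γ (16278 genes), 48% of genes changed 1.25-fold were found, 78% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 8 of 16006 unchanged genes were called. For the difference of responses these were 30%, 66%, 92% and 100%, with 9 of 16006 unchanged genes called. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, no low-count filter, at least 5 CPM in 3 libraries, only the compared libraries, the replicate number as a block, each library left out in turn and a log2 fold change of at least 1. For lists they were camera with an estimated correlation, fry, the block and each library left out, and for blocks 25 or 100 genes and an estimated correlation. Upper-quartile scaling, no scaling, a correction of blocks for GC content and length, and tests without the called blocks or without the MHC window of chromosome 6 were added after the data were seen. R 4.3.3 and Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9) were used. The log2 scale of the plots of 6 genes has a pseudocount of 0.5 CPM.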

Results

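RNA sequencing read counts were available for 12 libraries of THP-1, a human monocytic leukaemia cell line that phorbol ester (PMA) turns into macrophage-like cells. The cells were either wild type or edited with CRISPR/Cas9 at SDC3, which encodes syndecan-3, a cell-surface proteoglycan that carries heparan sulphate chains. All cultures received 20 ng/ml PMA for 24 h and then fresh medium, and recombinant human interferon gamma (IFN-γ) was added to part of them the next day. This gave 4 groups of 3 libraries: SDC3-knockout and wild-type cells, each with and without IFN-γ. The labels gave neither the dose and duration of IFN-γ nor the number and identity of the edited lines. Assigned counts ranged from 23616738 to 29426415 a library. They averaged 28425667 ± 866684 (SD, n = 3) in the knockout with IFN-γ and 27663769 ± 1751990 in the untreated knockout. The wild type had 26487625 ± 1609501 with IFN-γ and 26527121 ± 2754887 without it. Between 21529 and 23426 genes had a count in a library, and 17119 genes were tested. Over the 10747 genes at 5 counts-per-million (CPM) or more, the first principal component held 76.6% of the variance and the second 18.5%. Nothing in the labels said that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

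SDC3 lies on the minus strand of chromosome 1 at 30869467 to 30908761 (hg38). Its transcript was lower in the knockout libraries but still present in every one of them. With IFN-γ, SDC3 stood at 237, 237 and 244 CPM in the 3 knockout libraries and at 578, 590 and 572 CPM in the 3 wild-type libraries. Without IFN-γ, the values were 49.9, 48.2 and 43.9 CPM in the knockout against 196, 252 and 242 CPM in the wild type. By edgeR's quasi-likelihood test, SDC3 in the knockout was at 41.2% of the wild-type level with IFN-γ (log2 fold change -1.28, SE 0.06, adjusted p = 3.4e-18) and at 20.6% without it (log2 fold change -2.28, SE 0.06, adjusted p = 9.2e-24). IFN-γ raised SDC3 itself, by 1.33 on the log2 scale (SE 0.06, adjusted p = 1.1e-19) in the wild type and by 2.34 (SE 0.06, adjusted p = 2.4e-25) in the knockout. The counts cover all exons of the gene and the edited position was not given, so they check the direction of the labels and say nothing about the protein. The 20 tested neighbours of SDC3 had median log2 fold changes of 0.06 with IFN-γ and 0.04 without it.

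**Figure D1:**
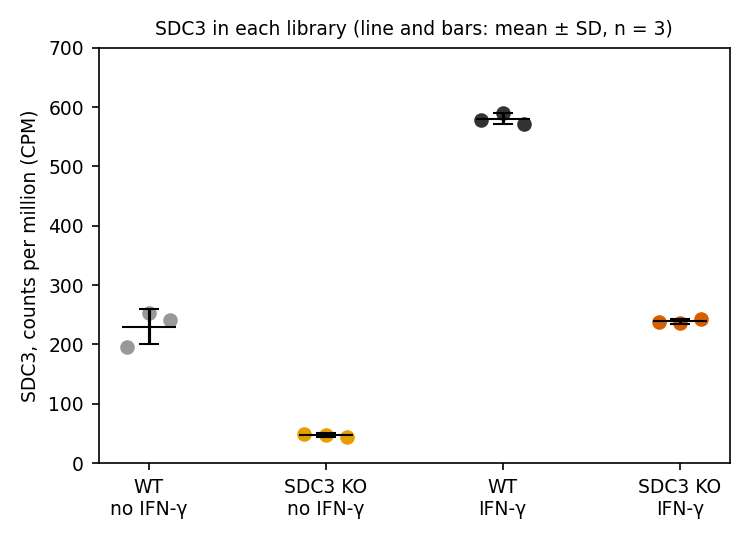
SDC3 CPM (vertical axis, from 0) in the 3 libraries of each group, with wild type in grey and black, SDC3 knockout in orange and red, and lines and bars for the mean and SD. The 3 knockout libraries lie at 43.9 to 49.9 CPM without IFN-γ and at 237 to 244 CPM with it, below the wild-type libraries of the same treatment (196 to 252 and 572 to 590 CPM).

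The comparison named in the design was knockout against wild type with IFN-γ. IFN-γ-treated knockout macrophages held far less transcript of the monocyte-attracting chemokine CCL2 and of the surface receptor CD93, and more transcript of the T-cell-attracting chemokines CXCL9, CXCL10 and CXCL11. CCL2 averaged 2.95 ± 0.186 CPM (SD, n = 3) against 58.0 ± 3.46 CPM in the wild type (log2 fold change -4.30, SE 0.13, adjusted p = 1.4e-23, edgeR). CXCL10 averaged 655 ± 69.1 against 277 ± 39.2 CPM (log2 fold change 1.24, SE 0.07, adjusted p = 1.7e-15), CXCL11 was higher by 1.42 (SE 0.13, adjusted p = 1.5e-10) and CXCL9 by 0.81 (SE 0.06, adjusted p = 6.5e-13). Genes of S, G2 and M phase were lower in the knockout (47 of 50, median log2 fold change -1.48), and type I interferon-stimulated genes were higher (43 of 49, median 0.44). In all, 3919 genes were higher and 4153 lower in the knockout, 47.2% of those tested, and 374 and 1224 of these differed by at least 1 on the log2 scale. Genes higher made up 48.6% of the calls with TMM scaling and 35.6% (2887 higher, 5213 lower) with library totals alone, which shifted the median gene by -0.08.

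Among the genes with the largest differences, the acute-phase genes ORM2 and ORM1 were higher in the knockout. ORM2 was at 7.15 against 0.692 CPM (log2 fold change 3.35, SE 0.28, adjusted p = 4.1e-13, edgeR) and ORM1 at 95.2 against 15.2 CPM (2.65, SE 0.10, adjusted p = 1.0e-19). ORM1 and ORM2 are near-identical copies, so the division of reads between them is uncertain. The neutrophil granule proteases PRTN3 (2.69, SE 0.17, adjusted p = 4.8e-16) and CTSG (2.53, SE 0.13, adjusted p = 8.2e-18), the matrix metalloproteinase MMP7 (59.2 against 12.3 CPM, SE of the log2 fold change 0.13, adjusted p = 1.2e-15) and TNFAIP6 (2.53, SE 0.19, adjusted p = 4.2e-13) were also higher. CD93 (chromosome 20, 23079349 to 23086340, minus strand, in a lower block of that chromosome) had 2 counts over the 3 knockout libraries and 2515 over the 3 wild-type libraries, a ratio of 1276 with an exact 95% counting interval of 353 to 10545. IGF2BP1, an RNA-binding protein gene, had no count in the knockout and 22.9 CPM in the wild type, at least 576-fold lower against a floor of 3 counts over the group. TSPYL5 was at least 187-fold and PTPN13 at least 130-fold lower in the same way. These intervals and floors cover counting error only. Because mates were counted separately, the counts of CD93 can come from 1 fragment, so the interval is too narrow and the floors are too low. The chemokine CCL7 (-6.17, SE 0.51, adjusted p = 6.9e-16) and the chemerin receptor CMKLR1 (-4.65, SE 0.28, adjusted p = 1.9e-17) were also lower.

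**Figure D2:**
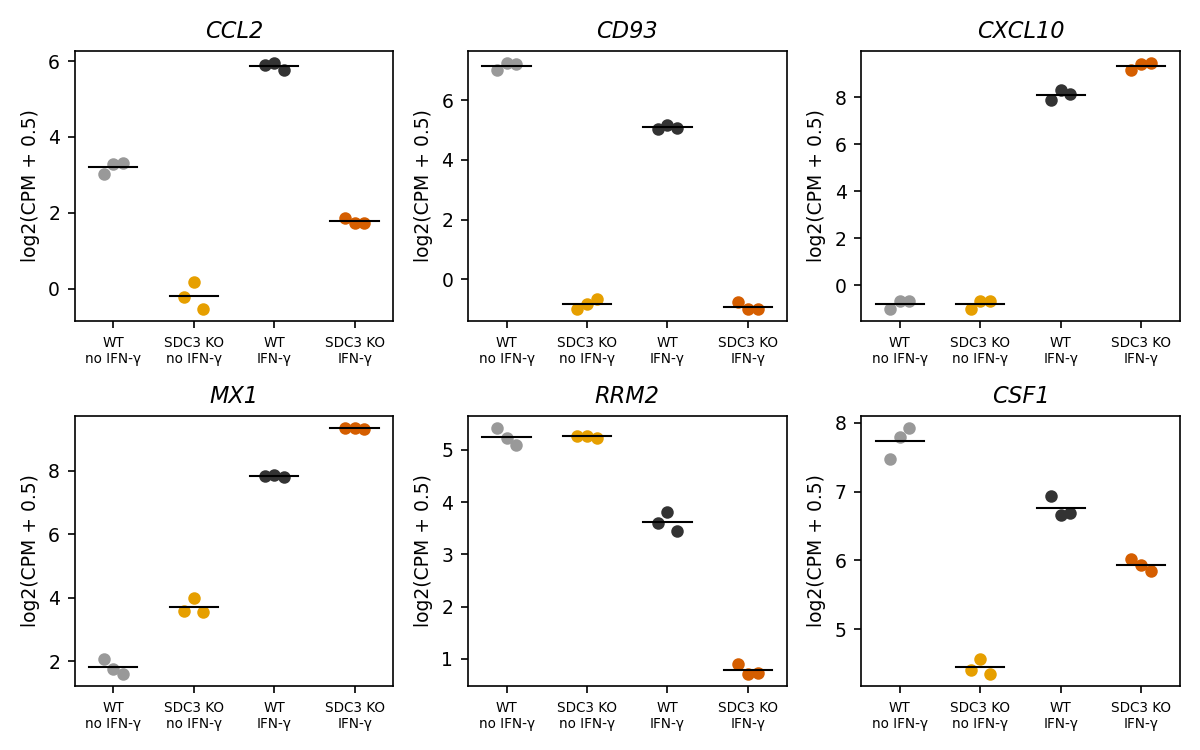
Level of 6 genes in each of the 12 libraries, as log2 of CPM plus 0.5 (vertical axes, not starting at 0); points are libraries and lines are group means. CCL2 and CD93 lie lower in the SDC3 knockout with and without IFN-γ, CXCL10 and MX1 are induced by IFN-γ in both genotypes to higher levels in the knockout, RRM2 is alike in the untreated groups and lowest in the treated knockout, and CSF1 falls with IFN-γ in the wild type and rises in the knockout.

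Interferon-related lists were higher in the IFN-γ-treated knockout as a whole. Of the 43 tested IFN-γ-induced effectors, 35 were higher and 2 lower (35 and 2 adjusted over the list alone; median 0.36, camera adjusted p = 3.6e-13). The effectors higher included the checkpoint ligand CD274 (0.64, SE 0.04, adjusted p = 2.2e-14), the tryptophan-degrading enzyme IDO1 (8.18 against 4.45 CPM, 0.88, SE 0.18, adjusted p = 2.0e-04) and GBP5 (0.11, SE 0.04, adjusted p = 0.026). The call of GBP5 was lost with at least 5 CPM required (adjusted p = 0.061), with upper-quartile scaling (0.069), without scaling (0.58), and without KO_IFNG replicate 1 (0.061), WT_IFNG replicate 1 (0.071) or WT_IFNG replicate 2 (0.098). The 2 effectors lower were P2RY14 (-1.23, SE 0.07, adjusted p = 4.9e-15) and PLAAT4 (-0.50, SE 0.06, adjusted p = 1.2e-08). Type I interferon-stimulated genes had 43 members higher and 0 lower (44 and 0 adjusted over the list alone; camera adjusted p = 1.6e-29), led by the antiviral genes RSAD2 (2.04, SE 0.06, adjusted p = 6.7e-23) and MX1 (1.51, SE 0.05, adjusted p = 1.6e-20).

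In the IFN-γ signalling list, 12 of 20 members were higher and 4 lower (the same over the list alone; median 0.16, camera adjusted p = 0.031). The IFN-γ signalling list had adjusted p = 0.10 with an estimated correlation. The transcription factor IRF1 (0.22, SE 0.04, adjusted p = 2.4e-06) and the receptor chain IFNGR2 (0.55, SE 0.05, adjusted p = 1.2e-11) were higher, and the class II transactivator CIITA was lower (-0.49, SE 0.06, adjusted p = 1.3e-08). IFNGR2 and MX1 lie in the run of neighbouring chromosome 21 genes that stood higher in the knockout in both treatments. MHC class I presentation genes were higher in 13 of 19 cases and lower in 1 (13 and 1 adjusted over the list alone; median 0.23, camera adjusted p = 0.038; 0.051 without WT_IFNG replicate 1), among them NLRC5 (0.50, SE 0.04, adjusted p = 5.6e-12) and the peptide transporter TAP1 (0.65, SE 0.13, adjusted p = 1.4e-04). The class I list had adjusted p = 0.28 with an estimated correlation. MHC class II presentation genes leaned the other way, with 5 of 20 higher and 9 lower (5 and 10 adjusted over the list alone; median -0.32, camera adjusted p = 0.0057), including HLA-DPB1 (-1.25, SE 0.21, adjusted p = 7.6e-06) and the protease LGMN (-2.28, SE 0.08, adjusted p = 7.7e-21). The class II list had adjusted p = 0.13 with an estimated correlation. Counts in the MHC window of chromosome 6 (28 to 34 Mb) scattered more between replicates than elsewhere, with a median SD of log2 CPM of 0.140 over 72 genes against 0.0794 in the rest of the genome. Part of the window was almost uncounted: 4 of 11 class I and 3 of 13 class II list members there had under 30 counts in every library (a limit set after the counts were seen), TAP2 at most 1. The class I and II list values therefore leave out or barely count some of their core genes. As an example of the scatter, TAPBP had from 22 to 1395 counts a library, and its higher level in the knockout (2.01, SE 0.63, adjusted p = 0.0088) was not called by DESeq2 (adjusted p = 0.25) or without WT_IFNG replicate 1 (0.068) or 2 (0.064). TAP1 also lies in that window, and its replicates overlapped. With IFN-γ it had 24524 to 45199 counts in the knockout and 16246 to 25395 in the wild type. Without the genes of that window, the class II list was no longer called and its direction turned (camera adjusted p = 0.987), while the class I list stayed called (0.045).

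Pro-inflammatory cytokines and chemokines had 11 of 23 members lower and 3 higher (the same over the list alone; median -0.20, camera adjusted p = 6.1e-06). Beside CCL2 and CCL7, IL1B was lower (-1.70, SE 0.13, adjusted p = 8.8e-13), and TNF had 4 counts over the 3 knockout libraries against 187 over the wild-type libraries (-5.45, SE 0.87, adjusted p = 1.0e-09). TNF lies in the chromosome 6 window (31575567 to 31578336), where DDX39B had 0 to 10 and CSNK2B 0 to 18 counts a library, 2 genes chosen after their counts were seen, so the level of TNF is uncertain in every comparison. The neutrophil chemokine CXCL8 was higher (0.83, SE 0.09, adjusted p = 3.1e-09), and IL6 was too low to be tested in any comparison. Genes of M2-type and anti-inflammatory macrophages had 20 of 40 members lower and 12 higher (13 higher adjusted over the list alone; median -0.28, camera adjusted p = 1.6e-04). Among them the complement gene C1QA (27.1 against 155 CPM, -2.52, SE 0.07, adjusted p = 1.3e-22) and the transcription factor MAF (-2.57, SE 0.15, adjusted p = 3.6e-16) were lower, and the scavenger receptor STAB1 (1.10, SE 0.07, adjusted p = 1.9e-14) and VSIG4 (1.09, SE 0.11, adjusted p = 1.3e-09) higher.

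The cell cycle list had the lowest median of all called lists (0 higher, 47 lower; 0 and 48 adjusted over the list alone; camera adjusted p = 3.2e-41), with the replication genes CDC45 (-3.56, SE 0.27, adjusted p = 3.6e-15) and RRM2 (-3.28, SE 0.18, adjusted p = 5.3e-18) as examples. Unfolded protein and integrated stress response genes were higher in 22 of 28 cases and lower in 5 (the same over the list alone; median 0.29, camera adjusted p = 2.5e-06), led by VLDLR (1.07, SE 0.05, adjusted p = 7.5e-17) and CHAC1 (0.84, SE 0.07, adjusted p = 3.7e-11). TRIB3, a target of the same response, was lower (-0.47, SE 0.05, adjusted p = 6.0e-09) and lies in a lower run of chromosome 20 genes. Cholesterol genes were higher in 17 of 24 cases and lower in 1 (median 0.28, camera adjusted p = 7.5e-04). The lanosterol synthase gene LSS was at 0.71 (SE 0.08, adjusted p = 5.1e-09) and lies in the higher run of chromosome 21 genes. The cholesterol list had adjusted p = 0.14 with an estimated correlation. NF-kB pathway genes were higher in 15 of 29 cases and lower in 5 (median 0.20, camera adjusted p = 8.0e-04), among them SOD2 (0.91, SE 0.04, adjusted p = 1.7e-19) and RELB (1.27, SE 0.06, adjusted p = 1.1e-17), the latter within a higher run of chromosome 19 genes. The NF-kB list had adjusted p = 0.15 with an estimated correlation. For these 2 lists the counts adjusted over the list alone were the same. Markers of undifferentiated monoblasts and granulocyte granules were higher in 12 of 19 cases and lower in 5, also over the list alone (median 0.36, camera adjusted p = 1.6e-04). The granule list had adjusted p = 0.13 with an estimated correlation. PRTN3 and CTSG led them, while lysozyme, LYZ, was lower (-1.21, SE 0.04, adjusted p = 4.7e-22) and lies in a lower run of chromosome 12 genes.

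Several smaller list differences were called in the IFN-γ-treated cells with less margin. The M1-type list had 9 of 19 members higher and 4 lower (9 and 6 adjusted over the list alone; camera adjusted p = 0.037; 0.056 without WT_IFNG replicate 3). FCGR2A was at 1.00 (SE 0.04, adjusted p = 2.5e-18) and CD86 at -0.76 (SE 0.05, adjusted p = 8.1e-15). The M1-type list had adjusted p = 0.10 with an estimated correlation. Its median was 0.17 and its mean -0.03, against an upward test. Toll-like receptor and inflammasome genes had 14 of 36 higher and 8 lower (15 and 8 adjusted over the list alone; median 0.13, camera adjusted p = 0.042; 0.061 without WT_IFNG replicate 3). AIM2 was at 0.91 (SE 0.05, adjusted p = 1.5e-16) and MEFV at 0.90 (SE 0.07, adjusted p = 9.8e-13). The Toll-like receptor list had adjusted p = 0.13 with an estimated correlation. Integrins and adhesion genes had 17 of 38 higher and 7 lower (the same over the list alone; median 0.11, camera adjusted p = 0.044; 0.058 without WT_IFNG replicate 1 and 0.061 without replicate 3). VCAM1 was at 1.253 (SE 0.09, adjusted p = 8.5e-13) and ITGB5 at -1.57 (SE 0.05, adjusted p = 5.7e-21). The integrin list had adjusted p = 0.15 with an estimated correlation. FCGR2A and AIM2 lie in a higher run of chromosome 1 genes and CD86 and ITGB5 in lower blocks of chromosome 3. Without the genes of such runs, none of these 3 lists was called by camera (0.061, 0.072 and 0.072). Of 4 tested epithelial markers, 2 were higher and 0 lower (the same over the list alone; camera adjusted p = 0.024), and leaving out any 1 of the 6 libraries ended the call (0.072 to 0.22). The epithelial list had adjusted p = 0.10 with an estimated correlation. They were MUC1 (147 against 65.0 CPM), which also lies in the chromosome 1 run, and CLDN7 (0.39, SE 0.08, adjusted p = 6.8e-05).

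Syndecans and other heparan sulphate proteoglycans were not called as a list (9 of 22 higher, 7 lower; 9 and 8 adjusted over the list alone; camera adjusted p = 0.46). Among the syndecans, SDC2 was lower (148 against 242 CPM, -0.71, SE 0.04, adjusted p = 1.4e-15) and SDC4 higher (76.5 against 58.0 CPM, 0.40, SE 0.05, adjusted p = 6.0e-08). SDC1 had 0 counts in the knockout against 13 in the wild type, at least 4.40-fold lower (adjusted p = 0.0032). The basement membrane proteoglycan HSPG2 (0.93, SE 0.08, adjusted p = 3.6e-11) and the glypican GPC3 (1.73, SE 0.11, adjusted p = 1.7e-14) were higher. Heparan sulphate synthesis and remodelling was not called either (8 of 28 higher, 10 lower; 8 and 11 adjusted over the list alone; camera adjusted p = 0.48), with the sulphatase SULF2 at -2.12 (SE 0.15, adjusted p = 6.1e-14) and the polymerase EXT2 at 0.63 (SE 0.06, adjusted p = 2.0e-10). Further lists not called by camera were chemokine receptors (10 of 23 higher, 8 lower, adjusted p = 0.20), Fc and scavenger receptors (12 and 15 of 36, 0.65, but called at 0.034 without the genes of the called blocks), matrix proteases (16 and 9 of 32, 0.067), glycolysis (6 and 12 of 24, 0.11) and p53 targets (6 and 13 of 26, 0.21). The remaining ones were lipid efflux (7 and 6 of 26, 0.65; 8 and 6 adjusted over the list alone), oxidative phosphorylation (12 and 8 of 40, 0.83; 13 and 9), PMA-driven differentiation (6 and 12 of 23, 0.73) and immediate early and heat shock genes (9 and 6 of 19, 0.75; 9 and 7). Markers of lymphocytes (2 higher, 6 lower of 11, adjusted p = 0.20), of fibroblast, endothelial or HEK293-type cells (1 and 5 of 9, 0.40; 1 and 6 adjusted over the list alone) and of erythroid cells (0 and 2 of 5, 0.20) were not called by camera. Where no list-alone count is given, it equalled the count over all genes.

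**Figure D3:**
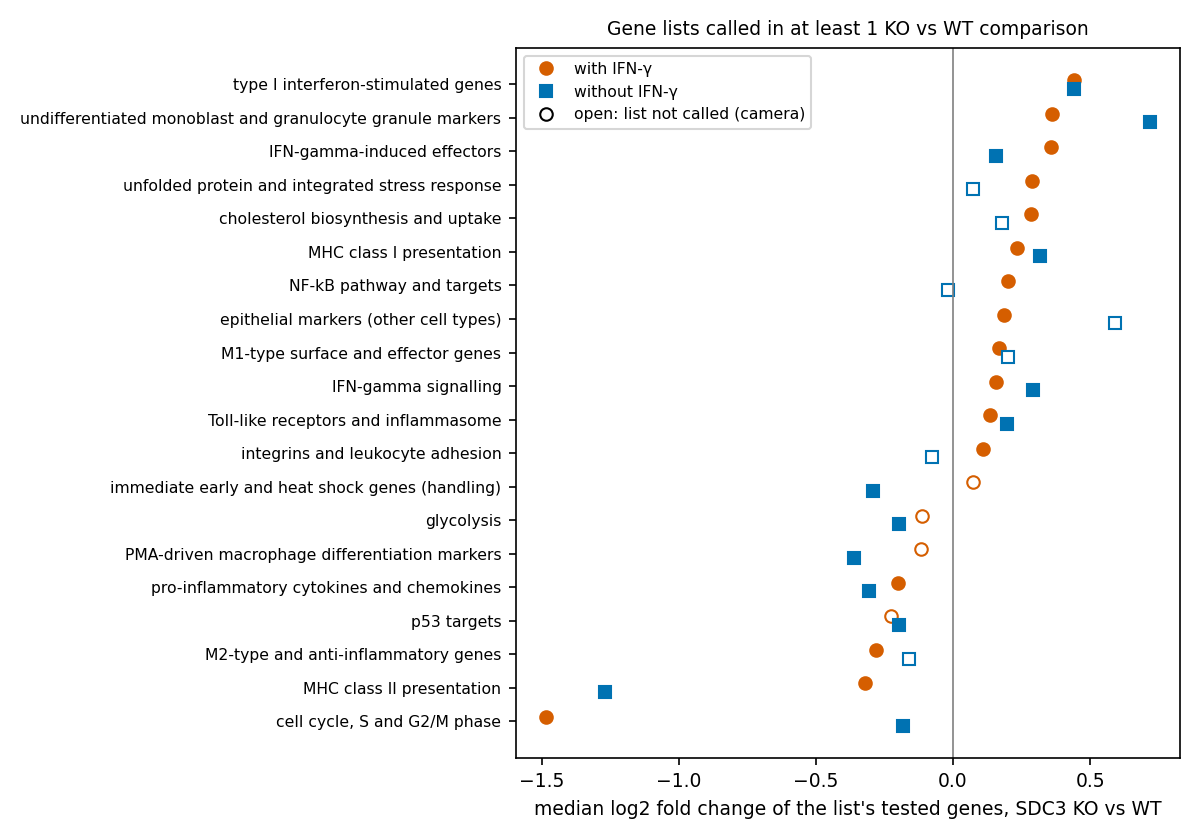
Median log2 fold change of each gene list, SDC3 knockout against wild type (horizontal axis), with IFN-γ (circles) and without it (squares), for lists called by camera in at least 1 of the 2 comparisons; open symbols were not called. The cell cycle list lies at -1.48 with IFN-γ and -0.18 without it, MHC class II presentation at -0.32 and -1.27, and type I interferon-stimulated genes at 0.44 in both.

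Knockout and wild type were next compared without IFN-γ, after PMA alone. The untreated knockout held much less of the macrophage growth factor CSF1, of CCL2 and of CD93, and more of the acute-phase gene ORM1 and of the stem cell factor receptor KIT. CSF1 averaged 21.3 against 214 CPM (-3.33, SE 0.09, adjusted p = 2.7e-24, edgeR), CCL2 0.397 against 8.75 CPM (-4.44, SE 0.27, adjusted p = 7.7e-19) and CD93 0.0643 against 144 CPM (-10.98, SE 0.66, adjusted p = 1.5e-30). KIT averaged 42.8 against 6.95 CPM (2.64, SE 0.13, adjusted p = 5.6e-17) and ORM1 73.6 against 12.3 CPM (2.60, SE 0.11, adjusted p = 1.5e-19). In all, 4343 genes were higher and 4240 lower in the knockout, 50.1% of those tested, and 518 and 1044 of these differed by at least 1 on the log2 scale. Also higher were PADI2, a protein-citrullinating enzyme (277 against 60.5 CPM, 2.20, SE 0.07, adjusted p = 4.4e-22), and MMP7 (2.32, SE 0.14, adjusted p = 2.4e-15). The lectin COLEC12 (0.596 against 28.5 CPM, -5.56, SE 0.22, adjusted p = 4.5e-23) and NAV3 (4.95 against 119 CPM, -4.59, SE 0.11, adjusted p = 2.2e-26) were lower, and lie in lower runs of chromosomes 18 and 12.

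Interferon genes were already higher in the untreated knockout. Type I interferon-stimulated genes had 34 of 49 members higher and 1 lower, also over the list alone (median 0.44, or 0.39 with a member at 0 counts set to its bound; camera adjusted p = 2.3e-09), with MX1 (2.07, SE 0.12, adjusted p = 3.3e-16) and IFI6 (378 against 100.1 CPM, 1.92, SE 0.08, adjusted p = 7.9e-19) among the highest. The type I interferon list had adjusted p = 0.079 with an estimated correlation. IFN-γ signalling had 12 of 20 higher and 3 lower, also over the list alone (median 0.29, camera adjusted p = 3.3e-04), with NLRC5 (1.04, SE 0.05, adjusted p = 1.4e-18) and IRF1 (0.70, adjusted p = 2.7e-15). CIITA was lower (1.62 against 2.33 CPM, -0.57, SE 0.18, adjusted p = 0.010), a call lost with only the 6 compared libraries in the fit (0.065), without KO_untreated replicate 3 (0.14) or without WT_untreated replicate 2 (0.11). Of 43 IFN-γ-induced effectors, 21 were higher and 9 lower (22 and 9 adjusted over the list alone; median 0.16, camera adjusted p = 0.015). The effector list had adjusted p = 0.21 with an estimated correlation. GBP4 (1.23, SE 0.05, adjusted p = 3.6e-19), LGALS3BP (1.20, SE 0.04, adjusted p = 1.5e-21) and CD274 (1.76 against 0.960 CPM, 0.89, SE 0.17, adjusted p = 3.6e-05) were higher, and SLAMF7 (-1.97, SE 0.07, adjusted p = 1.5e-20) and GBP1 (-0.996, SE 0.07, adjusted p = 5.6e-13) lower. GBP5 was higher (0.25, SE 0.08, adjusted p = 0.011), but not by limma-voom (0.086), with only the compared libraries (0.12), or without KO_untreated replicate 3 (0.11) or WT_untreated replicate 3 (0.24). CXCL9 had 4 counts and CXCL10 8 counts over each genotype's 3 untreated libraries (adjusted p = 0.99 for both), and IDO1 had 0 in both genotypes. MHC class I genes were higher in 13 of 19 cases and lower in 1, also over the list alone (median 0.32, camera adjusted p = 9.3e-04). The class I list had adjusted p = 0.20 with an estimated correlation.

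MHC class II presentation genes were lower in the untreated knockout in 12 of 20 cases and higher in 4 (4 and 13 adjusted over the list alone; median -1.27, camera adjusted p = 2.5e-05). The class II list had adjusted p = 0.079 with an estimated correlation. HLA-DQB1 (2.97 against 18.7 CPM, -2.66, SE 0.10, adjusted p = 3.9e-21) and LGMN (-3.40, SE 0.12, adjusted p = 2.2e-22) were lower, while CTSS, in the chromosome 1 run, was higher (0.70, SE 0.04, adjusted p = 5.0e-15). Without the noisy chromosome 6 window the class II list was not called (camera adjusted p = 0.63). Pro-inflammatory cytokines and chemokines had 10 of 23 members lower and 2 higher, also over the list alone (median -0.31, camera adjusted p = 4.6e-04). Beside CCL2 and CSF1, IL1B (-0.46, SE 0.14, adjusted p = 0.0072) and TNF (10 against 55 counts, -2.43, SE 0.62, adjusted p = 4.3e-04) were lower and CXCL8 (0.80, SE 0.08, adjusted p = 8.8e-10) and IL18 (0.31, SE 0.07, adjusted p = 8.2e-04) higher. Immediate early and heat shock genes, a list fixed in advance as a sign of sample handling, were lower in 13 of 19 cases and higher in 4 (5 and 13 adjusted over the list alone; median -0.29, camera adjusted p = 1.7e-07), led by EGR1 (-2.13, SE 0.17, adjusted p = 3.3e-12) and DUSP2 (-1.83, SE 0.17, adjusted p = 6.5e-11), while FOS was higher (0.33, SE 0.06, adjusted p = 3.6e-05). The immediate early list had adjusted p = 0.092 with an estimated correlation. Its heat shock members HSPA1A and HSPA1B lie in the chromosome 6 window, had 0 counts in every library and could not be tested. Granule and monoblast markers were higher in 14 of 19 cases and lower in 4, also over the list alone (median 0.72, camera adjusted p = 6.1e-07), with KIT and S100A12 (1.21, SE 0.10, adjusted p = 2.1e-11) higher and MS4A3 (-0.83, SE 0.15, adjusted p = 3.3e-05) lower. The granule list had adjusted p = 0.079 with an estimated correlation.

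A further 5 lists were called in the untreated comparison. PMA-driven differentiation markers had 8 of 23 higher and 14 lower (median -0.36, camera adjusted p = 0.0047). TIMP1 was at 0.78 (SE 0.04, adjusted p = 6.1e-17) and EGR2 at -1.20 (SE 0.05, adjusted p = 1.1e-18). The PMA list had adjusted p = 0.34 with an estimated correlation. Cell cycle genes were lower in 28 of 50 cases and higher in 0 (median -0.18, camera adjusted p = 0.0066). AURKB was at -0.92 (SE 0.11, adjusted p = 4.2e-08) and TYMS at -0.69 (SE 0.07, adjusted p = 1.8e-09), both in lower runs. The cell cycle list had adjusted p = 0.38 with an estimated correlation. Glycolysis genes were lower in 14 of 24 cases and higher in 6 (median -0.20, camera adjusted p = 0.0099; 0.27 without the runs). ENO2 was at -2.58 (SE 0.13, adjusted p = 1.4e-17). The glycolysis list had adjusted p = 0.34 with an estimated correlation. The p53 targets were lower in 13 of 26 cases and higher in 4 (median -0.20, camera adjusted p = 0.044; 0.14 without the runs, 0.055 without WT_untreated replicate 1 and 0.064 without replicate 2). PLK3 was at -1.28 (SE 0.08, adjusted p = 3.6e-14). The p53 list had adjusted p = 0.12 with an estimated correlation. Toll-like receptor and inflammasome genes were higher in 20 of 36 cases and lower in 7 (median 0.20, camera adjusted p = 0.045; 0.058 without the runs, 0.064 without WT_untreated replicate 2 and 0.052 without replicate 3). MEFV was at 1.61 (SE 0.07, adjusted p = 6.0e-18). The Toll-like receptor list had adjusted p = 0.19 with an estimated correlation. Adjusted over the list alone, the counts of these 5 lists were the same. Proteoglycans (7 of 22 higher, 9 lower, adjusted p = 0.53) and heparan sulphate synthesis (8 and 9 of 28, 0.64) were not called by camera, with equal counts adjusted over the list alone. SDC2 (-0.47, adjusted p = 9.7e-12), SDC4 (-0.54, adjusted p = 6.8e-11), SULF2 (-2.66, SE 0.11, adjusted p = 3.1e-19) and SDC1 (24 against 72 counts, -1.57, SE 0.51, adjusted p = 0.0081; 0.085 without WT_untreated replicate 3) were lower.

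Across the 17119 tested genes, which are not independent replicates, the differences between knockout and wild type with and without IFN-γ correlated with r = 0.715 (Spearman's rho 0.664). The 2 comparisons share no library. Both set edited against wild-type cells, so a difference between the lines other than SDC3 would recur in both. CCL2, CD93, ORM1, MMP7, MX1 and SULF2 differed in the same direction in both. In all, 2770 genes were higher in both, where independent lists would share 994, and 2919 were lower in both, where independent lists would share 1029. Another 255 genes, SDC4 among them, were called in opposite directions.

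Genes that lie side by side on a chromosome differed together. Of 331 blocks of 50 consecutive tested genes, 47 were called by camera in the same direction in both knockout comparisons, 16 higher and 31 lower, and 3 were called with an estimated correlation. On chromosome 1, 8 of 36 blocks between 148435105 and 182589256 were higher, and their 400 genes, FCGR2A, AIM2, SLAMF7 and MUC1 among them, had median log2 fold changes of 0.45 with IFN-γ and 0.41 without it. All 3 blocks of chromosome 21 (184 genes, IFNGR2 and MX1 among them) were higher, at 0.45 and 0.50. All 4 blocks of chromosome 18 (COLEC12 and TYMS among their genes) were lower, at -0.39 in both. Chromosome 12 had 10 of 18 blocks lower (LYZ, NAV3 and BCAT1 among their genes, about -0.36 in both). Chromosome 17 had 7 of 21 lower (AURKB and CXCL16 among their genes, -0.44 and -0.36). On chromosome 19, 3 of 24 blocks were higher, at 0.49 and 0.48. Of these, 2 lay side by side from 44105463 to 48287608, with RELB among their genes, and 1 from 51410021 to 53159075. The 2 blocks between them were not called (medians -0.085 and -0.17 with IFN-γ), and the next block, to 55384598, was lower (-0.26 and -0.18). That block overlaps the leukocyte receptor complex (54 to 56 Mb), where 28.9% of 38 genes scattered between replicates above the 95th percentile of the rest, LAIR1 from 324 to 1653 counts a library. CCL2 itself (chromosome 17, 34255218 to 34257203, plus strand) lay outside the called blocks.

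**Figure D4:**
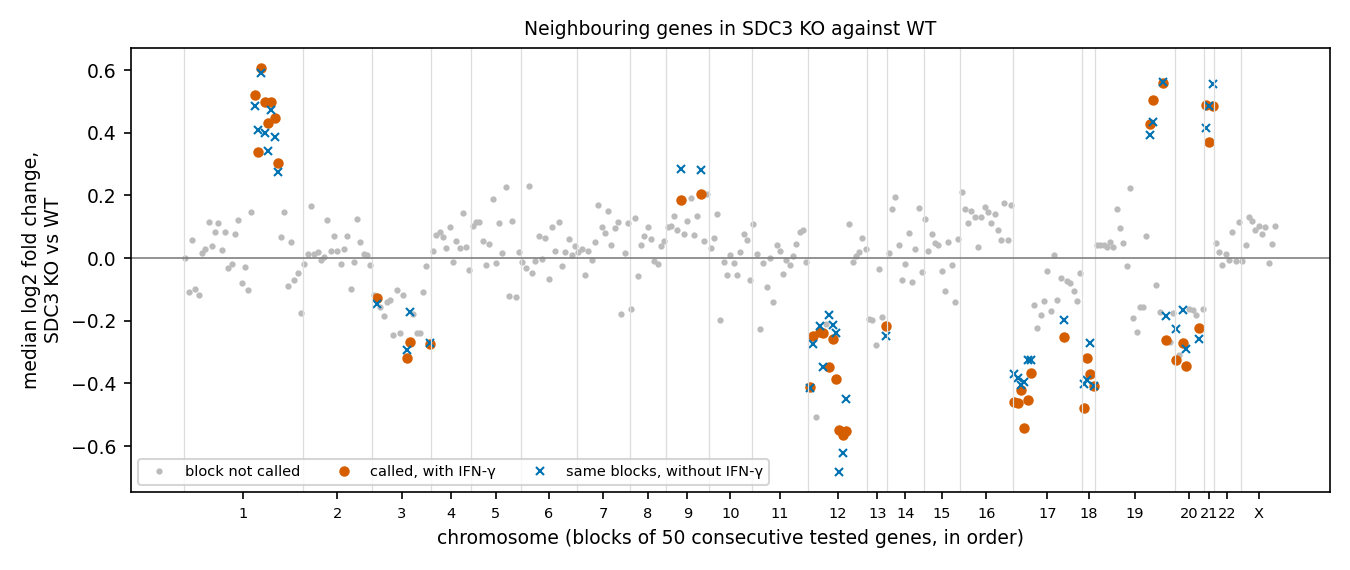
Median log2 fold change, SDC3 knockout against wild type (vertical axis), of blocks of 50 consecutive tested genes in chromosome order (horizontal axis). The 47 blocks called in the same direction in both treatments are coloured by treatment, and grey blocks were not called; chromosome 21 and part of chromosomes 1 and 19 lie higher, and chromosome 18 and parts of chromosomes 12 and 17 lie lower.

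The response to IFN-γ in wild-type cells gives the background for the genotype comparisons. IFN-γ switched on the chemokines CXCL9 and CXCL10, the antigen presentation genes and the guanylate-binding protein GBP5, and lowered genes of the cell cycle and of granulocyte granules. CXCL9 rose from 4 counts over 3 libraries to 391 ± 38.8 CPM (SD, n = 3; log2 fold change 12.94, SE 0.93, adjusted p = 2.5e-34, edgeR), CXCL10 to 277 CPM (11.51, SE 0.77, adjusted p = 1.5e-31) and GBP5 from 6.80 to 3420 CPM (8.97, SE 0.07, adjusted p = 7.6e-41). The apolipoprotein L gene APOL4 (10.19, SE 0.21, adjusted p = 1.1e-39) and the complement gene C1QB (9.74, SE 0.28, adjusted p = 1.8e-36) also rose from near 0. IDO1 rose from 0 counts to 4.45 CPM, at least 130-fold, and FAM107A from 0 to 7.12 CPM, at least 211-fold. The granule protease PRTN3 (-4.22, SE 0.16, adjusted p = 9.6e-24), the progenitor transcription factor MYB (-4.12, SE 0.10, adjusted p = 1.1e-27) and haptoglobin, HP (-5.27, SE 0.23, adjusted p = 2.8e-24), fell. In all, 4896 genes rose and 4770 fell, 56.5% of those tested. Genes that rose made up 50.7% of the calls, but 37.5% (3751 and 6246) with upper-quartile scaling and 25.1% (2767 and 8260) with library totals alone, which shifted the median gene by -0.11 and -0.25.

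All 43 tested IFN-γ-induced effectors (median 4.28, camera adjusted p = 8.3e-280) and all 49 type I interferon-stimulated genes (median 3.01, 4.9e-191) rose in the wild type, CD274 by 8.20 (SE 0.14, adjusted p = 7.3e-38). In IFN-γ signalling 17 of 20 rose and 1 fell (median 1.88, camera adjusted p = 4.4e-50). IRF1 was at 4.83 (SE 0.04, adjusted p = 1.8e-38), CIITA at 6.83 (SE 0.13, adjusted p = 1.1e-33) and the receptor chain IFNGR1 at -0.46 (SE 0.04, adjusted p = 5.2e-11). MHC class II presentation rose in 17 of 20 cases and fell in 1 (median 3.36, camera adjusted p = 6.5e-53), HLA-DQA1 by 7.93 (SE 0.10, adjusted p = 3.9e-38). Without the chromosome 6 window 8 of 9 class II genes rose, with a median of 0.90. Class I rose in 18 of 19 cases and fell in 0 (median 1.79, camera adjusted p = 9.9e-21), TAP1 by 4.42 (SE 0.15, adjusted p = 1.7e-21). M1-type genes rose in 15 of 19 cases and fell in 2 (median 1.19, camera adjusted p = 1.2e-20), CD40 by 3.43, and Toll-like receptor and inflammasome genes rose in 25 of 36 and fell in 5 (26 and 6 adjusted over the list alone; median 0.87, camera adjusted p = 6.8e-13), AIM2 by 6.36. Stress response genes rose in 19 of 28 cases and fell in 5 (median 0.40, camera adjusted p = 9.0e-13), with the serine and asparagine synthesis genes PSAT1 (4.58) and ASNS (4.84) highest, and M2-type genes rose in 23 of 40 and fell in 13 (14 adjusted over the list alone; median 0.47, camera adjusted p = 1.1e-05). All 50 cell cycle genes fell (median -1.94, camera adjusted p = 7.0e-39), as did 17 of 19 granule markers, with 1 higher (median -1.70, camera adjusted p = 1.3e-13). Where no list-alone count is given here, it equalled the count over all genes.

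Lists that changed less in the wild type included lipid genes, of which 15 of 26 fell and 8 rose (median -0.31, camera adjusted p = 0.0034). LPL was at -2.93 and FABP4 at -3.66. Pro-inflammatory genes rose in 12 of 23 cases and fell in 7 (median 0.28, camera adjusted p = 0.019; 0.053 without WT_untreated replicate 1). In that list CCL2 rose by 2.72 (SE 0.10, adjusted p = 8.2e-22), IL1B by 1.58 (SE 0.12, adjusted p = 7.8e-13) and TNF by 2.02 (SE 0.37, adjusted p = 1.8e-05), while CXCL8 (-0.42, SE 0.09, adjusted p = 1.7e-04) and CSF1 (-0.98, SE 0.08, adjusted p = 5.3e-13) fell. NF-kB genes (16 of 29 rose, 7 fell, 0.0044), epithelial markers (3 and 0 of 4, 0.019), PMA-driven markers (7 and 14 of 23, 0.024) and Fc and scavenger receptors (21 and 12 of 36, 0.026) were called by camera, but adjusted p = 0.19, 0.065, 0.47 and 0.092 with an estimated correlation. Leaving out WT_untreated replicate 1 or any WT_IFNG library ended the call of the epithelial list, MUC1 leading it (0.059 to 0.11). Proteoglycans (6 and 10 of 22, adjusted p = 0.16) and heparan sulphate synthesis (5 and 12 of 28, 0.17; 5 and 13 adjusted over the list alone) were not called by camera. SDC4 (-0.54, adjusted p = 3.5e-11), SDC2 (-0.32, adjusted p = 1.8e-08), SDC1 (-2.16, SE 0.59, adjusted p = 0.0011) and XYLT1, which starts heparan sulphate chains (-2.31, SE 0.07, adjusted p = 1.5e-24), fell. The other list-alone counts were the same.

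In knockout cells IFN-γ induced the same chemokines, CXCL9 by 13.78 (SE 0.93, adjusted p = 1.4e-35, edgeR), CXCL10 by 12.78 (SE 0.77, adjusted p = 1.6e-33) and CXCL11 from 0 counts to 44.2 CPM, at least 1333-fold. Cell cycle genes fell further than in the wild type, with a median of -3.41. IDO1 rose from 0 counts to 8.18 CPM, at least 246-fold, GBP5 by 8.83 (adjusted p = 7.6e-41), CD274 by 7.95 (SE 0.11, adjusted p = 1.2e-38), IRF1 by 4.35 (adjusted p = 8.5e-38) and CIITA by 6.91 (SE 0.15, adjusted p = 4.6e-33). MYB (-5.96, SE 0.14, adjusted p = 6.5e-31), the coagulation factor gene F13A1 (-5.93, SE 0.62, adjusted p = 1.0e-15) and the cell cycle gene E2F8 (-5.76, SE 0.38, adjusted p = 6.9e-21) fell. MS4A3 went from 497 counts over the group to 2, a ratio of 208 with an exact 95% counting interval of 57.2 to 1721, which is too narrow where both mates of a fragment were counted. In all, 5005 genes rose and 5451 fell, 61.1% of those tested. Genes that rose made up 47.9% of the calls, but 36.4% (3928 and 6864) with upper-quartile scaling and 23.4% (2787 and 9141) with library totals alone, which shifted the median gene by -0.12 and -0.30.

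All 43 effectors (median 4.28, camera adjusted p = 2.7e-252) and all 49 type I interferon-stimulated genes (median 3.33, 1.0e-180) rose in the knockout, RSAD2 by 7.75. IFN-γ signalling (17 of 20 rose, 1 fell, median 1.68, camera adjusted p = 1.8e-38), MHC class II (18 and 1 of 20, median 4.19, or 3.70 with members at 0 counts set to their bound, 4.2e-48) and class I (18 and 0 of 19, median 1.53, 3.8e-15) rose, HLA-DQA1 by 10.19 (SE 0.31, adjusted p = 5.3e-37). Without the chromosome 6 window 8 of 9 class II genes rose, with a median of 1.30. M1-type (15 and 4 of 19, median 1.15, camera adjusted p = 1.2e-17), stress response (22 and 4 of 28, 22 and 5 adjusted over the list alone, median 0.74, 4.0e-17), Toll-like receptor (24 and 6 of 36, median 0.74, 1.6e-10) and M2-type genes (20 and 15 of 40, median 0.42, 0.0045) rose. PSAT1 was at 5.35, SOD2 at 4.06 and TLR7 at 4.05. All 50 cell cycle genes (camera adjusted p = 4.6e-59) and 18 of 19 granule markers with 0 higher (median -1.81, 1.8e-13) fell. NF-kB genes (19 and 3 of 29, median 0.45, camera adjusted p = 4.1e-06) and epithelial markers (3 and 0 of 4, 0.0058; 0.051 without KO_IFNG replicate 1) were called, and pro-inflammatory genes (12 and 6 of 23, 0.099), proteoglycans (7 and 10 of 22, 0.64) and heparan sulphate synthesis (6 and 14 of 28, 0.19; 6 and 15 adjusted over the list alone) were not. The NF-kB list had adjusted p = 0.068 with an estimated correlation. The other list-alone counts were the same. CCL2 rose by 2.87 (SE 0.28, adjusted p = 2.9e-12), CSF1 by 1.51 (SE 0.09, adjusted p = 6.7e-16) and SDC4 by 0.39 (adjusted p = 3.0e-08; 0.086 without scaling), while CXCL8 (-0.40, adjusted p = 8.0e-05) and SDC2 (-0.56, adjusted p = 8.4e-14) fell. SDC1 went from 24 counts to 0, at least 6.69-fold lower (adjusted p = 2.8e-04). TNF had 10 counts untreated and 4 treated (-1.004, SE 0.999, adjusted p = 0.35), and IL1B was at 0.34 (SE 0.14, adjusted p = 0.041), a call lost under 6 other settings (0.051 to 0.79) and without KO_IFNG replicate 2 (0.10) or 3 (0.069) or KO_untreated replicate 1 (0.13) or 2 (0.079).

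The difference between the 2 responses was tested directly. Cell cycle genes fell further in the knockout (42 of 50, 0 the other way; 44 and 0 adjusted over the list alone; median difference -1.37 on the log2 scale, camera adjusted p = 2.7e-83), for example RRM2, which went from 37.8 to 1.22 CPM in the knockout and from 37.7 to 11.9 CPM in the wild type (-3.29, SE 0.20, adjusted p = 2.5e-15, edgeR). CSF1 rose with IFN-γ in the knockout and fell in the wild type (2.49, SE 0.12, adjusted p = 1.5e-16), and SDC3 rose more in the knockout (1.00, SE 0.08, adjusted p = 9.9e-11). MHC class II genes gained more in the knockout, from a lower start (8 of 20, 1 the other way; 10 and 1 adjusted over the list alone; median 0.80, camera adjusted p = 2.1e-11). The class II median difference was not recomputed with members at 0 counts set to their bound. Doing so for 2 members took the median response in the knockout from 4.19 to 3.70. Without the chromosome 6 window, 2 of 9 class II genes were higher and 1 lower (median 0.10, camera adjusted p = 0.036, adjusted p = 0.11 with an estimated correlation). Across genes the 2 responses correlated with r = 0.871 (Spearman's rho 0.813), 4083 genes rose in both and 3866 fell in both, and 121 were called in opposite directions. The response was higher in the knockout for 1302 genes and lower for 1345, 15.5% of those tested; 49.2% of the calls were higher with TMM scaling, 56.6% (1499 and 1150) with RLE size factors and 35.0% (1000 and 1855) with library totals alone, so which direction held more calls depended on the scaling. Of the 1345 genes, 592 fell in both genotypes and 240 rose in both; of the 1302 genes, 679 rose in both and 155 fell in both.

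Among the largest single differences, the response was higher in the knockout for ANK2 (3.87, SE 0.47, adjusted p = 1.1e-10), VCAM1 (3.54, SE 0.69, adjusted p = 2.4e-05), the phosphatase DUSP5 (2.94, SE 0.17, adjusted p = 8.3e-15), BCAT1 (2.89, SE 0.11, adjusted p = 1.2e-19) and SLAMF7 (2.46, SE 0.09, adjusted p = 2.9e-19). It was lower for the replication and cell cycle genes E2F8 (-3.76, SE 0.40, adjusted p = 1.2e-10), CDCA7 (-3.71, SE 0.47, adjusted p = 2.0e-09), NEIL3 (-3.47, SE 0.47, adjusted p = 3.4e-08), MCM10 (-3.33, SE 0.39, adjusted p = 2.1e-09), CDC45 (-3.15, SE 0.29, adjusted p = 3.7e-11) and MYBL2 (-3.02, SE 0.17, adjusted p = 9.3e-16). Of the fixed panel, IRF1 (-0.47, SE 0.05, adjusted p = 7.2e-08), IL1B (-1.24, SE 0.19, adjusted p = 1.1e-05), TNF (-3.02, SE 1.07, adjusted p = 0.034) and SDC2 (-0.24, SE 0.06, adjusted p = 0.0028) had lower responses in the knockout, and the response of SDC4 was higher by 0.93 (SE 0.07, adjusted p = 1.1e-11). The call of TNF was lost by limma-voom (adjusted p = 0.12) and without KO_IFNG replicate 3 (0.099), KO_untreated replicate 1 (0.11) or 3 (0.24) or WT_IFNG replicate 2 (0.063). The differences for CIITA (0.08, adjusted p = 0.85), GBP5 (-0.14, adjusted p = 0.34), CD274 (-0.26, adjusted p = 0.42), CXCL8 (0.02, adjusted p = 0.94) and CCL2 (0.15, adjusted p = 0.80) were not called by edgeR. Nor were those for CXCL9 (0.84, adjusted p = 0.75), CXCL10 (1.27, adjusted p = 0.51) and SDC1 (adjusted p = 0.14), but these had very few counts in a group. At such counts the differences are poorly measured, so equal responses cannot be read from them. IDO1 had 0 counts in both untreated groups, so its difference could not be measured.

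Among the lists, the immediate early and heat shock genes of the handling list responded more positively in the knockout (11 of 19, 2 the other way; 12 and 2 adjusted over the list alone; median 0.34, camera adjusted p = 7.3e-15). This list was lower in the untreated knockout (median -0.29, camera adjusted p = 1.7e-07) and not called with IFN-γ (median 0.07, camera adjusted p = 0.75). The difference of responses therefore lay mainly in the untreated libraries, and whether sample handling differed there was not tested. ATF3 was at 2.06 (SE 0.07, adjusted p = 1.2e-19), DUSP2 at 1.58 (SE 0.29, adjusted p = 1.8e-04) and FOS at -0.47 (SE 0.09, adjusted p = 3.8e-04). Stress response genes also responded more positively in the knockout (10 of 28, 4 the other way, 11 and 6 adjusted over the list alone, median 0.10, camera adjusted p = 2.8e-08). PHGDH was at 1.18 (SE 0.10, adjusted p = 4.6e-10). NF-kB genes (10 of 29, 1 the other way, also over the list alone; median 0.16, camera adjusted p = 3.5e-08) included NFKBIA (1.23, SE 0.11, adjusted p = 3.3e-10) and TNFAIP3 (1.22, SE 0.10, adjusted p = 5.2e-11). The NF-kB list had adjusted p = 0.062 with an estimated correlation. The class II list held HLA-DQA1 (2.267, SE 0.33, adjusted p = 9.9e-08) and HLA-DQB1 (1.94, SE 0.11, adjusted p = 6.8e-15). MHC class I had 6 of 19 lower and 0 higher (1 and 7 adjusted over the list alone; median -0.15, camera adjusted p = 0.034). The class I list had adjusted p = 0.32 with an estimated correlation. The class I call was lost without the chromosome 6 window (0.097) and without KO_IFNG replicate 3 (0.073), KO_untreated replicate 1 (0.094), WT_IFNG replicate 3 (0.073) or WT_untreated replicate 2 (0.073). IFN-γ signalling had 2 of 20 higher and 8 lower, also over the list alone (median -0.04, camera adjusted p = 0.0072). IRF8 was at -0.71 (SE 0.07, adjusted p = 8.1e-10) and BATF2 at -0.66 (SE 0.16, adjusted p = 0.0031). The IFN-γ signalling list had adjusted p = 0.061 with an estimated correlation. The effectors had 13 of 43 higher and 7 lower, also over the list alone (median 0.05, camera adjusted p = 0.0028). GBP1 was at 1.40 (SE 0.09, adjusted p = 6.4e-14) and LGALS3BP at -1.05 (SE 0.05, adjusted p = 2.5e-15). The effector list had adjusted p = 0.11 with an estimated correlation.

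Further lists were called with small medians. PMA-driven markers had 9 of 23 higher and 2 lower (10 and 3 adjusted over the list alone; median 0.06, camera adjusted p = 4.1e-04, adjusted p = 0.28 with an estimated correlation). FABP4 was at 1.19 (SE 0.16, adjusted p = 1.9e-06). Matrix proteases had 8 of 32 higher and 3 lower (8 and 4 adjusted over the list alone; median 0.03, camera adjusted p = 0.0028, adjusted p = 0.081 with an estimated correlation). TIMP3 was at 1.45 (SE 0.10, adjusted p = 1.3e-12) and MMP19 at 0.72 (SE 0.07, adjusted p = 1.2e-09). Proteoglycans had 6 of 22 higher and 4 lower, also over the list alone (camera adjusted p = 0.017), with a median just below 0 and a mean of -0.07 against an upward test. The proteoglycan list had adjusted p = 0.069 with an estimated correlation. Lipid genes (7 and 3 of 26; 8 and 3 adjusted over the list alone; median 0.02, camera adjusted p = 0.026) included LPL at 1.07 (SE 0.09, adjusted p = 1.6e-10). The lipid list had adjusted p = 0.078 with an estimated correlation. Cholesterol genes (7 and 1 of 24; 9 and 2 adjusted over the list alone; median 0.11, camera adjusted p = 0.025; 0.11 without WT_IFNG replicate 1) included SQLE at 0.67 (SE 0.09, adjusted p = 9.6e-07). The cholesterol list had adjusted p = 0.32 with an estimated correlation. Type I interferon-stimulated genes (17 and 13 of 49, 0.22, but 0.029 without KO_untreated replicate 2; 19 and 13 adjusted over the list alone), pro-inflammatory genes (4 and 3 of 23, 0.092, but 0.033 without the chromosome 6 window) and heparan sulphate synthesis (2 and 2 of 28, 0.77; 4 and 2) were not called by camera.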

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

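The tests of the SDC3 transcript, of library scaling, of undifferentiated cells, of GC content and of copy number were chosen only after the results were seen; the tests on other splits of the samples were chosen before.

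The difference between the IFN-γ responses of knockout and wild-type cells drew attention for each gene and list given here, by edgeR or camera. The response was higher in the knockout for SDC3 (1.00), ANK2 (3.87), VCAM1 (3.54), DUSP5 (2.94), BCAT1 (2.89), CSF1 (2.49), SLAMF7 (2.46), HLA-DQA1 (2.267), HLA-DQB1 (1.94), ATF3 (2.06), PHGDH (1.18), DUSP2 (1.58), GBP1 (1.40), NFKBIA (1.23), TNFAIP3 (1.22), FABP4 (1.19), LPL (1.07), TIMP3 (1.45), MMP19 (0.72), SQLE (0.67) and SDC4 (0.93). It was lower for E2F8 (-3.76), CDCA7 (-3.71), NEIL3 (-3.47), MCM10 (-3.33), RRM2 (-3.29), CDC45 (-3.15), MYBL2 (-3.02), FOS (-0.47), LGALS3BP (-1.05), IRF8 (-0.71), BATF2 (-0.66), IRF1 (-0.47), TNF (-3.02), IL1B (-1.24) and SDC2 (-0.24). HLA-DQA1, HLA-DQB1 and TNF lie in the chromosome 6 window, where counts were uncertain. The lists had median differences of -1.37 (cell cycle), 0.34 (immediate early and heat shock genes, the handling list), 0.80 (MHC class II), 0.10 (stress response), 0.16 (NF-kB), 0.057 (PMA-driven markers), 0.052 (effectors), 0.026 (matrix proteases), -0.038 (IFN-γ signalling), -0.0037 (proteoglycans), 0.11 (cholesterol), 0.021 (lipid genes) and -0.15 (MHC class I).

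SDC3 transcript remained in every knockout library. If wild-type cells of the kind sequenced here had supplied it, they would have brought every wild-type transcript at the SDC3 share or more. Yet 4 of 10190 genes, CD93, IGF2BP1, NAV3 and CCL2, lay under 0.25 of that share in both conditions, CD93 at 0.0799% and 0.0447% of the wild-type level against 41.2% and 20.6% for SDC3. The number needed to argue against this source was first set at 5 and was lowered to 3 after 4 were found, so under the first number the test would have decided nothing. The table holds 0 other genes that overlap SDC3, which argues against reads of a neighbour, while an edited transcript that is still made and unedited cells of the knockout line itself were not tested and stay open.

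Cell cycle genes fell further with IFN-γ in the knockout. The weakest median difference over 4 scalings was -1.35, which argues against library scaling. Undifferentiated cells left in the wild-type cultures would have put granule markers lower in the knockout, yet 12 of 19 were higher with IFN-γ (median 0.36, lower quartile -0.82), which goes against them; they stay open because the difference of responses, which takes out the untreated levels, had 9 of these markers lower and 5 higher (median -0.36). In 1 of 100 groupings of the 12 libraries, the real one, edgeR called as many as 2647 genes for the difference of responses (highest other 2206). At an unadjusted p under 0.05, several other groupings gave more genes than the real 4578, up to 6112. Random groupings mix genotypes and treatments within a group, which widens the spread there, so the count of 2647 cannot exclude chance. For the 13 lists chance cannot be excluded either (5 of 100 groupings, highest other 13). Whether loss of SDC3 or another difference between the lines may lie behind the pattern was not tested.

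Neighbouring genes shifted together between knockout and wild type. A candidate explanation is a copy number difference between the lines: 27 pairs of adjacent blocks were called in the same direction, where permuted blocks gave 3.30 on average and at most 11 (p = 0.0001, the smallest that 10000 permutations can give). For this check each gene's edgeR p-value was turned into a signed z-score. Transcript GC content and length together explained 0.438% of the variance of these scores with IFN-γ and 0.408% without it. Camera run on the scores called 58 blocks before and 61 after correction, 46 of the 47 among them. These values argue against such a trend as the whole cause. Of 100 pairs of splits only 1, the real one, gave as many as 47 blocks. The highest other gave 46, so the count hardly sets the real grouping apart, and it does not exclude chance. Regional regulation of expression without a copy number change was not tested and stays open, and no DNA data were used here.

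The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05, and 1 split, the real one, reached each real value. With IFN-γ, edgeR called 8072 genes between genotypes against 0 in the highest other split (9001 against 658 at an unadjusted p under 0.05), and camera called 16 lists against 8. Without IFN-γ these were 8583 genes against 0 (9406 against 1003) and 13 lists against 7. For IFN-γ in the wild type they were 9666 against 0 (10326 against 658) and 17 lists against 11, and in the knockout 10456 against 0 (10983 against 391) and 13 lists against 12. No other tool was run on the splits. The correlation of the genotype effects, 0.715, was reached by 1 of 100 pairs of splits, the real one, with 0.496 the highest other. This argues against a random division of the libraries as its source. A difference between the lines other than loss of SDC3 would give the same result, so the splits cannot tell these apart.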

How the results depend on the processing

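Upper-quartile scaling, no scaling, the GC content and length correction and the tests without the called blocks or the chromosome 6 window were chosen only after the results were seen. Of 215 named gene values 202 were called, and 8 of these lost the call at least once over 3432 values under alternatives, as given beside them. With a log2 fold change of at least 1, higher and lower genes numbered 374 and 1224 (knockout against wild type with IFN-γ), 518 and 1044 (without), 1268 and 1508 (IFN-γ in the wild type), 1455 and 1872 (in the knockout) and 175 and 283 (difference of responses). Without scaling, IFN-γ gave 2767 and 8260 genes in the wild type and 2787 and 9141 in the knockout. Every other count of genes from DESeq2, limma-voom, other scalings and other filters was within 1.5 times the reported one. With an estimated correlation, the lists called fell from 16 to 6 with IFN-γ, from 13 to 2 without it and from 13 to 4 for the difference of responses; fry, which does not compare a list with other genes, called 27, 26, 27 and 29 lists in the first 4 comparisons. The correlation of the genotype effects was 0.786 with at least 5 CPM in 3 libraries, and 29 blocks of 100 genes or 3 blocks of 50 with an estimated correlation were called. Fewer blocks of 100 exist; otherwise the cause was not tested. Lists not called by camera also gained calls: the glycolysis list in the difference of responses without WT_untreated replicate 1 (adjusted p = 0.042), and Fc and scavenger receptors for IFN-γ in the knockout without KO_IFNG replicate 1, 2 or 3 (0.0496, 0.045 and 0.039). The MHC class II list with IFN-γ reversed without the chromosome 6 window (adjusted p = 0.987), and CXCL8 in the difference of responses, not called, went to -0.023 without scaling.

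Leaving out each library in turn gave 3548 to 3918 higher and 3559 to 3931 lower genes with IFN-γ, 3803 to 4195 and 3832 to 4148 without it, 4576 to 4760 and 4398 to 4547 for IFN-γ in the wild type, 4762 to 5011 and 4775 to 5111 in the knockout, and 1084 to 1361 and 941 to 1387 for the difference. SDC3 stayed within -1.29 to -1.24, -2.39 to -2.21, 1.23 to 1.41, 2.29 to 2.38 and 0.93 to 1.11. Values that were not called changed sign: CXCL9 (-0.49 to 0.47) and CXCL10 (-0.51 to 0.49) without IFN-γ, both near the floor where depth is the limit, and CIITA (-0.16 to 0.33), CXCL8 (-0.046 to 0.084) and CCL2 (-0.19 to 0.69) in the difference of responses; the cause was not tested.

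The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated from -0.149 to 0.252, those of other numbers from -0.175 to 0.240, and 4 of 12 libraries correlated best with their own number. With the replicate block, higher and lower genes were 3884 and 4099, 4304 and 4196, 4863 and 4737, 4982 and 5393, and 1275 and 1313, and no call of a named gene or list changed.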

Other observations

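The families described here were chosen after the results were seen, from 234 families of at least 8 genes with a shared symbol, tested by camera with adjustment over families. Large-subunit ribosomal protein genes (RPL) were lower in the knockout for 41 of 48 members and higher for 1, both with IFN-γ (median -0.28, adjusted p = 7.5e-07) and without it (median -0.23, adjusted p = 1.6e-04). RPL22, for example, was at 116 against 150 CPM with IFN-γ (log2 fold change -0.38, SE 0.05, adjusted p = 5.1e-08, edgeR). The RPL medians were lower under all 4 scalings (-0.36 to -0.26 and -0.26 to -0.23). Small-subunit genes (RPS) were lower for 26 of 43 members in both (medians -0.17 and -0.20, camera adjusted p = 0.035 and 0.048). They were higher for 6 members with IFN-γ and 7 without it. With an estimated correlation the RPL and RPS calls were lost (adjusted p = 0.99 and 0.96 for both families), and reads of these genes can be shared with their pseudogenes.

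Protocadherin beta genes (PCDHB), cell adhesion genes of 1 cluster on chromosome 5, were higher in the IFN-γ-treated knockout for 8 of 9 members (median 2.19, camera adjusted p = 0.0018, adjusted p = 0.26 with an estimated correlation) and for 4 of 9 without IFN-γ (median 0.53). The PCDHB median with IFN-γ was 2.11 to 2.21 over the 4 scalings. IFN-γ raised the proteasome beta subunit genes (PSMB) in the wild type (9 of 10, median 0.69, adjusted p = 6.4e-04, adjusted p = 0.60 with an estimated correlation) and in the knockout (10 of 10, median 0.80, adjusted p = 0.0013, adjusted p = 0.55 with an estimated correlation). The PARP family rose in 9 of 13 and fell in 3 in both genotypes (medians 0.78 and 1.34, adjusted p = 2.7e-10 and 3.0e-09).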
